A study of Homo sapiens with 44 samples.

How the data were processed

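Gene-level RNA-seq counts were analysed for 44 libraries made from the human lung adenocarcinoma cell line A549 and from xenograft tumours grown from it. Per the labels, polyA RNA was extracted with a QIAGEN RNeasy Plus Mini kit and libraries were made with a KAPA stranded mRNA-seq kit. The submitters' processing notes name bcl2fastq, HISAT2, HTSeq and the hg38 assembly, without versions. The deposited values are read counts per gene from HTSeq, in 3 tables for cultured cells, day 30 tumours and treated tumours. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that share reads with an antisense neighbour or a close paralog carry that uncertainty.

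Gene identifiers were looked up in GENCODE release 29 on GRCh38, and 58721 of 58721 identifiers matched in each table. Symbols and coordinates below come from that release. Total counts ran from 61168373 to 93444327 per library in cells, from 63243289 to 99593214 in day 30 tumours and from 61937591 to 82475298 in treated tumours. Intervals and floors on single genes cover counting error only, since reads without molecular identifiers are not independent molecules. How reads from host cells in the tumours were handled is not given in the sources used here.

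Groups were taken from the labels. The lines are WT, het1, het2 and homo, with 3 libraries each in culture and 4 each as tumours at day 30, and WT and het1 tumours given DMSO or SAHA for 4 weeks have 4 libraries each. SAHA is vorinostat, an inhibitor of histone deacetylases. Replicate numbers recur between groups, and whether they pair the libraries is not given in the sources used here. Residual correlations across genes between libraries with the same number ran from -0.16 to 0.11 in cells, from -0.21 to 0.17 in day 30 tumours and from -0.2 to 0.21 in treated tumours. Their medians were -0.01, 0 and -0.03, against 0, 0 and -0.01 for other pairs. This gave no sign of pairing, but groups of 3 or 4 libraries cannot exclude it. Among the 60 pairs of libraries within a group, 0 were identical.

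Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3, with all of its groups in the fit, TMM factors, filterByExpr and robust quasi-likelihood tests. This tested 21704 genes in cells, 22533 in day 30 tumours and 22586 in treated tumours. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. Log2 fold changes (log2FC) are given with the model's standard error (SE), and levels are CPM (counts scaled to a library total of 1e6 after TMM) as the mean ± SD over the libraries of a group. Each line was compared with WT, homo was compared with the mean of het1 and het2, SAHA was compared with DMSO in each line, and the difference between the 2 SAHA effects was tested as an interaction. The 12 comparisons and 31 gene lists were fixed before the data were examined, as were the rule for naming genes and all alternatives except those named as added.

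Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera compares a list with the other genes. Of 118 list calls, 14 were also called with an estimated correlation, and the report gives the adjusted p with an estimated correlation beside each list call it describes. Genes that differed between a line and WT in culture by at least 2-fold were tested as sets in the tumours of that line, and the het1 tumour genes in the treated tumours. Sharing between lines was compared with the number of genes that independent lists of the same sizes would share, and with 10 simulated sets of unchanged lines that used the same WT libraries.

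The named genes are EP300 and CREBBP in every comparison; up to 6 of the greatest rises and 6 of the greatest falls per comparison; up to 8 of each for genes shared by 3 lines; and up to 4 members with the smallest p of each list described. The greatest changes were taken among genes with a call, a mean of at least 5 CPM and no overlap between the libraries of the groups compared. For homo against the het lines and for the interaction the overlap rule was left out and up to 4 were taken each way. Clone names, pseudogenes, XIST and genes of the Y chromosome were left out, and 5 genes that the rule names are not reported here. Where a group had 0 counts of a gene, the fold is a bound from a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with its 95% exact binomial interval.

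The alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter at a mean of 1 CPM, a log2FC of at least 1, the replicate number as a block, only the groups compared, a covariate for host cells, fry in place of camera, an estimated correlation, and leaving out each library in turn. The covariate was the mean log2 CPM of the fibroblast, endothelial and myeloid marker lists. Leaving out treated tumours in pairs, and testing the het1 tumour genes for the SAHA change in WT, were added after seeing the data. The procedure was tested on simulated data with known changes: of 50 genes changed 1.5-fold, 92% were recovered in cells, 76% in day 30 tumours, 78% for SAHA in WT, 68% for SAHA in het1 and 62% for the interaction, and 4 to 14 unchanged genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.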

Results

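The series holds RNA-seq counts from A549 cells and from 3 A549 lines in which, per the series description, p300 lacks its TAZ2 domain, a part of this acetyltransferase that binds transcription factors. The lines are called het1, het2 and homo, and WT is the parental line. Cultured cells gave 12 libraries (3 per line), tumours collected at day 30 gave 16 (4 per line), and WT and het1 tumours treated with DMSO or SAHA for 4 weeks gave 16 (4 per group). All libraries held at least 61168373 counts. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples. Each genotype other than WT was present as a single line or, for the heterozygotes, as 2 lines, so a difference from WT joins the truncation with anything else that sets that line apart.

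EP300, which encodes p300 (ENSG00000100393, chromosome 22, 41091786 to 41180079), and its paralog CREBBP, which encodes CBP (ENSG00000005339, chromosome 16, 3725054 to 3880726), address whether the edited gene or its paralog differed in RNA level. In culture EP300 was at 115 ± 3.84 CPM in WT (n = 3) and rose to 185 ± 2.87 in het1 (log2FC 0.69), 153 ± 4.05 in het2 (0.42) and 190 ± 2.38 in homo (0.73). In day 30 tumours (n = 4) it rose from 88.7 ± 3.9 CPM in WT to 140 ± 3.22 in homo (log2FC 0.66, edgeR adjusted p = 6.81e-06). It stood at 102 ± 7.07 in het1 tumours (log2FC 0.21, adjusted p = 0.072) and 105 ± 19.8 in het2 tumours (0.24, 0.0367). The het1 difference was called without het1 tumour replicate 4 (log2FC 0.26). The het2 call was lost when any of WT replicates 0, 1, 2 and 4 or het2 replicates 0 and 1 was left out, with log2FC from 0.15 to 0.34 over the single omissions. Under DMSO, EP300 rose from 98.9 ± 8.55 to 128 ± 7.99 CPM in het1 (log2FC 0.37, adjusted p = 0.000575).

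CREBBP in culture was at 101 ± 2.36 CPM in WT, fell in het1 (log2FC -0.18, adjusted p = 1.25e-05), rose in homo (0.31, 2.59e-10) and had a log2FC of 0.05 in het2 (adjusted p = 0.211). In day 30 tumours it fell from 108 ± 4.55 CPM in WT to 65.5 ± 5.32 in het1 (log2FC -0.73, adjusted p = 2.81e-06). The fall to 89.4 ± 16 CPM in het2 tumours (log2FC -0.28, adjusted p = 0.0193) was lost without WT replicate 2, het2 replicate 3 or het2 replicate 4, with log2FC from -0.39 to -0.2. Homo tumours had a log2FC of -0.13 (adjusted p = 0.264). CREBBP fell in het1 tumours under DMSO (log2FC -0.41, adjusted p = 2.56e-05). SAHA left both genes uncalled in both lines, with log2FC from -0.06 to -0.01. Counts per gene cannot show where a transcript ends, so the truncation itself was not examined.

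**Figure D1:**
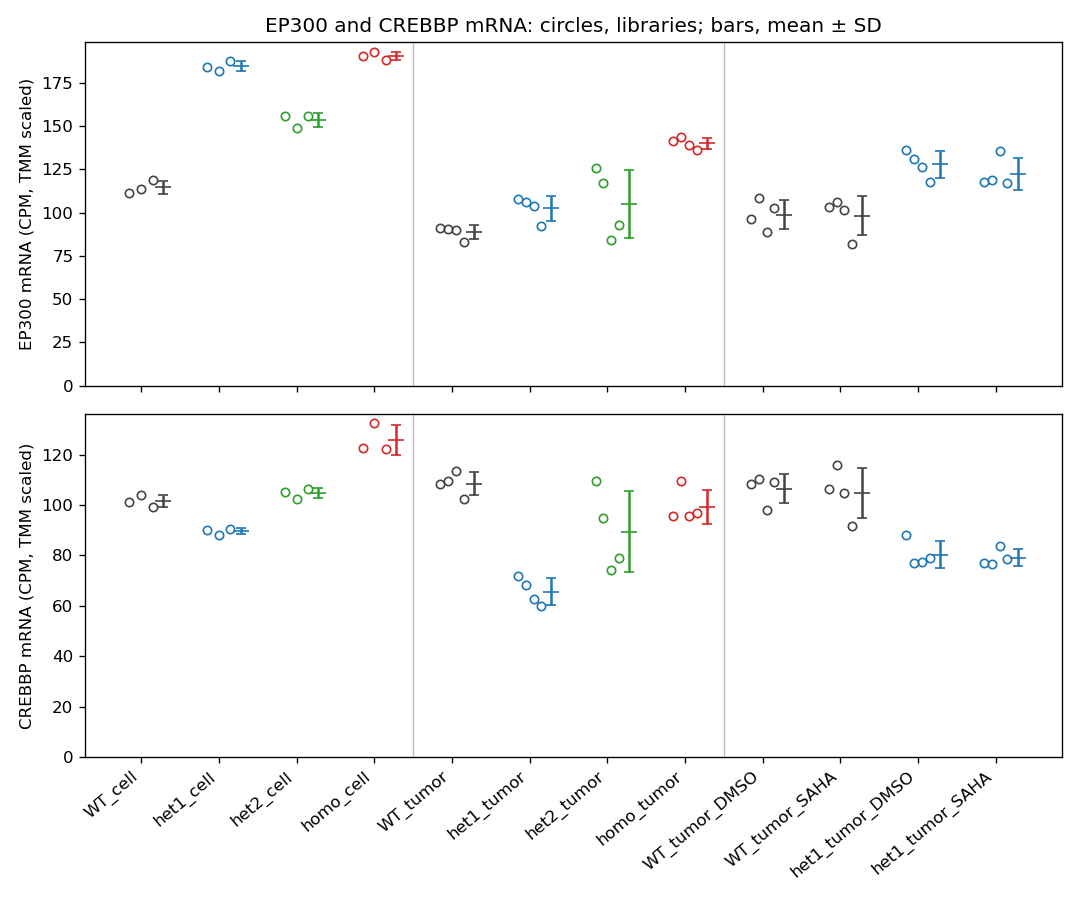
EP300 and CREBBP in CPM (vertical axes) in each of the 44 libraries of the 12 groups (horizontal axis). Points are libraries and bars are mean ± SD; EP300 means run from 88.7 CPM in WT tumours to 190 CPM in homo cells.

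The comparison of het1 with WT cells asks which genes the first heterozygous line expressed differently in culture (n = 3 per group). BHLHE41, a transcription factor gene, rose from 0.0768 ± 0.0172 to 17.1 ± 0.473 CPM (log2FC 7.77, SE 0.13), the neurosecretory protein gene SCG2 from 1.22 ± 0.141 to 207 ± 6.45 CPM (7.39, SE 0.053) and the receptor gene CALCRL from 0.411 ± 0.18 to 56.1 ± 4.27 CPM (7.02, SE 0.11). DAAM2 and MGAT4C, with 2 counts each over the WT libraries, were higher by ratios of 4250 (interval 1180 to 35100) and 3430 (949 to 28300). FAM155A rose to 15.6 ± 0.757 CPM (log2FC 7.63). The neurotrophin receptor gene NTRK3 fell from 39.9 ± 0.683 CPM to 0 counts, at least 3000-fold. The matrix proteoglycan gene VCAN fell from 93.1 ± 3.42 to 0.0533 ± 0.0133 CPM (log2FC -10.73), NPR3 by a log2FC of -10.53, the sialyltransferase gene ST6GAL2 by -9.82, the activin subunit gene INHBB by -9.06 and ANXA3 by -8.42. EdgeR called 6949 genes raised and 6691 lowered, of which 4253 changed at least 2-fold.

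NRF2 target genes were lower in het1 cells (median log2FC -0.64; 3 raised and 18 lowered of 22, and the same numbers adjusted over the list alone; camera adjusted p = 6.91e-10, and adjusted p = 0.00295 with an estimated correlation). The aldo-keto reductase gene AKR1B10 fell from 6170 ± 107 to 212 ± 3.11 CPM, AKR1C3 from 2530 ± 31.8 to 136 ± 2.69, AKR1C1 from 2150 ± 49 to 84.5 ± 1.09 and AKR1C2 from 3110 ± 34.6 to 154 ± 4.83. Basement membrane and matrix genes were lower (median -1.55; 2 raised and 17 lowered of 20; adjusted p = 1.44e-07, and adjusted p = 0.0281 with an estimated correlation), with COL4A6, COL4A2 and COL5A1 falling and COL6A1 rising 4.33-fold. Of 28 cell cycle genes, 25 fell and 2 rose (median -0.51; adjusted p = 6.91e-10, and adjusted p = 0.0414 with an estimated correlation), among them CCNA2, MCM4, AURKA and CDC20. MYC and ribosome biogenesis genes were lower too (16 of 18 lowered, 1 raised; adjusted p = 1.96e-07, and adjusted p = 0.0137 with an estimated correlation), including DKC1, NPM1, CAD and NCL. Epithelial genes had a median of -0.98 (5 raised, 11 lowered of 16; adjusted p = 0.0041, and adjusted p = 0.0656 with an estimated correlation): KRT8 fell from 3090 ± 84.7 to 1030 ± 27 CPM, and KRT18, KRT19 and ELF3 fell. Mesenchymal genes did not move the opposite way as a list (4 raised and 8 lowered of 18; median -0.31; adjusted p = 0.031, and adjusted p = 0.2 with an estimated correlation). FN1 fell 20-fold, and TGFBI, S100A4 and AXL fell.

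Het2 against WT cells asks the same of the second heterozygous line (n = 3 per group). The matricellular gene POSTN rose from 0 counts to 63.9 ± 0.966 CPM, at least 4700-fold over a floor of 3 counts, and the collagen gene COL14A1 rose from 2 counts to 212 ± 1.2 CPM, a ratio of 23400 (interval 6480 to 193000). SYT14 rose by a log2FC of 8.97 (SE 0.26), LRP1B by 8.85 (SE 0.15), the laminin gene LAMA1 by 8.45 (SE 0.14) and SLITRK4 by 8.31 (SE 0.22). The uroplakin gene UPK1B fell from 40.7 ± 1.29 CPM to 0 counts (at least 3380-fold) and ANKS4B from 18.3 ± 0.624 CPM to 0 counts (at least 1520-fold). ST6GAL2 fell by a log2FC of -11.44, the mucin gene MUC5AC by -10.91, C1orf116 by -9.77 and TM4SF4 by -8.77. EdgeR called 7625 genes raised and 7233 lowered, 5137 of them at least 2-fold.

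Epithelial genes were lower in het2 cells (median log2FC -1.63; 3 raised and 12 lowered of 16; adjusted p = 9.99e-05, and adjusted p = 0.0327 with an estimated correlation). ELF3 fell from 158 ± 3.62 to 16.1 ± 0.711 CPM and KRT19 from 71.2 ± 4.67 to 1.17 ± 0.0975 CPM. Fibroblast markers were higher in these cultures, which hold no host cells (median 2.35; 8 of 8 raised; adjusted p = 0.00134, and adjusted p = 0.0359 with an estimated correlation): COL1A1 rose from 5.81 ± 0.6 to 32.2 ± 0.963 CPM, and THY1 and ACTA2 rose. AKR1B10, AKR1C3, AKR1C2 and AKR1C1 fell again, by 30.5-fold, 18.6-fold, 14.6-fold and 8.53-fold, within an NRF2 list that was lower (7 raised, 14 lowered; adjusted p = 0.00109, and adjusted p = 0.0327 with an estimated correlation). Of the MYC and ribosome biogenesis genes 18 of 18 fell (median -0.57; adjusted p = 7.11e-10, and adjusted p = 0.00923 with an estimated correlation), ODC1 most by p. Cell cycle genes had 25 of 28 lowered (adjusted p = 1.81e-10, and adjusted p = 0.0327 with an estimated correlation). YAP target genes were lower (2 raised, 10 lowered of 12; adjusted p = 8.23e-05, and adjusted p = 0.061 with an estimated correlation), with AXL, AJUBA, NT5E and ANKRD1 falling. Of 12 secreted protease genes 10 rose, and MMP2 rose from 0.914 ± 0.258 to 25.5 ± 0.759 CPM while MMP7 fell 8.04-fold (adjusted p = 0.0102, and adjusted p = 0.231 with an estimated correlation). The protease inhibitor genes TIMP1 and TIMP2 were among those that rose.

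Homo against WT cells asks what the line labelled homo expressed differently (n = 3 per group). POSTN rose from 0 counts to 24.9 ± 1.32 CPM (at least 1830-fold), the MHC class II gene HLA-DPA1 to 20.4 ± 0.306 CPM (at least 1500-fold) and the guanylate cyclase subunit gene GUCY1A1 to 14.8 ± 1.22 CPM (at least 1090-fold). JAKMIP2 rose from 2 counts to 27.9 ± 1.21 CPM, a ratio of 3080 (interval 852 to 25400), LAMA1 by a log2FC of 10.43 and LRCH2 by 9.3. ANXA13 fell from 36.1 ± 1.43 CPM to 0 counts (at least 2480-fold), ANKS4B to 0 counts (at least 1250-fold) and the antisense transcript IGFL2-AS1 to 0 counts (at least 1140-fold). The adhesion gene CEACAM6 fell from 272 ± 10 CPM to 3 counts, a ratio of 18700 (interval 6410 to 90900). TM4SF4 fell by a log2FC of -11.92 and the keratin gene KRT19 by -11.42. EdgeR called 7685 genes raised and 7608 lowered, 5775 of them at least 2-fold.

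AKR1B10 fell in homo cells from 6170 ± 107 to 6.48 ± 0.349 CPM, 954-fold, and AKR1C3, AKR1C2 and AKR1C1 fell 203-fold, 203-fold and 98.8-fold. The NRF2 list had 4 raised and 17 lowered of 22 (median -0.88; adjusted p = 1.11e-07, and adjusted p = 0.00777 with an estimated correlation). In the MYC and ribosome biogenesis list 17 of 18 fell (adjusted p = 1.21e-07, and adjusted p = 0.0119 with an estimated correlation). Epithelial genes had a median of -2.66 (1 raised and 11 lowered of 16, 2 raised when adjusted over the list alone; adjusted p = 0.000405, and adjusted p = 0.0546 with an estimated correlation), and KRT7, KRT18 and KRT8 fell 11.4-fold, 6.85-fold and 7.58-fold. Stem cell associated genes had 9 of 11 lowered, among them CD44, SOX9, ALDH3A1 and NOTCH3 (adjusted p = 0.000501, and adjusted p = 0.0698 with an estimated correlation). Of 13 MHC class I antigen presentation genes 10 rose and 0 fell, with HLA-B rising from 8.74 ± 0.892 to 33 ± 0.622 CPM and HLA-E and HLA-C rising (adjusted p = 0.000405, and adjusted p = 0.158 with an estimated correlation). Cell cycle genes had 24 of 28 lowered, yet CCNE1 rose 2.34-fold (adjusted p = 1.11e-07, and adjusted p = 0.063 with an estimated correlation). Reads of HLA genes can be shared between paralogs.

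Genes that differed from WT the same way in het1, het2 and homo cells address whether the lines share a change. BHLHE41 was at 0.0768 CPM in WT and at 17.1, 18.5 and 43.6 CPM in the 3 lines (log2FC at least 7.77 in each), and LRCH2, CALCRL and CALHM5 rose by log2FC of at least 7.59, 6.3 and 6.14. HLA-DPA1 had 0 counts in WT and was at 2.33, 5.55 and 20.4 CPM. MGAT4C, COL14A1 and DAAM2, with 2 counts each in WT, reached at least 2.24, 1.21 and 0.847 CPM. ST6GAL2 fell from 138 ± 2.59 CPM by log2FC of -8.65 or further in every line, and MUC5AC, INHBB, KRT4, MGLL and TM4SF4 fell by -8.35, -8.01, -6.69, -6.47 and -5.83 or further. C1orf116 fell from 22.4 ± 1.4 CPM to 0.146 ± 0.108 CPM or less. EdgeR called 4554 genes raised in all 3 lines and 4570 lowered. Independent lists of the same sizes would share 864.4 and 781.6, and the simulated unchanged lines shared 0. Those lines were simulated with no change, so few calls were expected, and the 0 covers only noise in the shared WT libraries. A trait that set the WT line apart from all 3 lines would also be shared, and was not tested. Log2FC of pairs of lines correlated across genes with r = 0.69 (het1 and het2), 0.76 (het1 and homo) and 0.85 (het2 and homo), against 0.51, 0.5 and 0.5 in simulation, where the shared WT libraries alone produce a correlation. Covariances of the same pairs were 1.39, 1.82 and 2.37, against 0.0241, 0.024 and 0.0238 in simulation. Noise in the shared WT libraries thus gave a small part of the covariance. Genes are not independent replicates.

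Homo against the mean of het1 and het2 cells asks whether the line labelled homo differed from the heterozygous lines. MARCOL rose by a log2FC of 7.28 (SE 0.11), GUCY1A1 by 5.81, the metalloprotease gene MMP16 by 5.58 and JAKMIP2 by 5.45. CEACAM6 fell by a log2FC of -8.47, the fibrinogen gene FGA by -7.11 and the carboxylesterase gene CES1 by -6.55. LHX8 fell by -6.45 (SE 1.3) and was not called without het2 replicate 2 (log2FC -4.93). EdgeR called 5430 genes raised and 5396 lowered. NRF2 target genes were lower in homo than in the het lines (2 raised and 17 lowered of 22; adjusted p = 1.28e-11, and adjusted p = 0.00176 with an estimated correlation), with AKR1B10 lower 32.1-fold. Epithelial genes were lower too (11 of 16; adjusted p = 7.47e-05, and adjusted p = 0.0439 with an estimated correlation), with KRT7 at a log2FC of -2.25. The p53 targets CDKN1A, TNFRSF10B, FAS and ZMAT3 were lower (median of the list -0.24; adjusted p = 0.000331, and adjusted p = 0.207 with an estimated correlation).

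**Figure D2:**
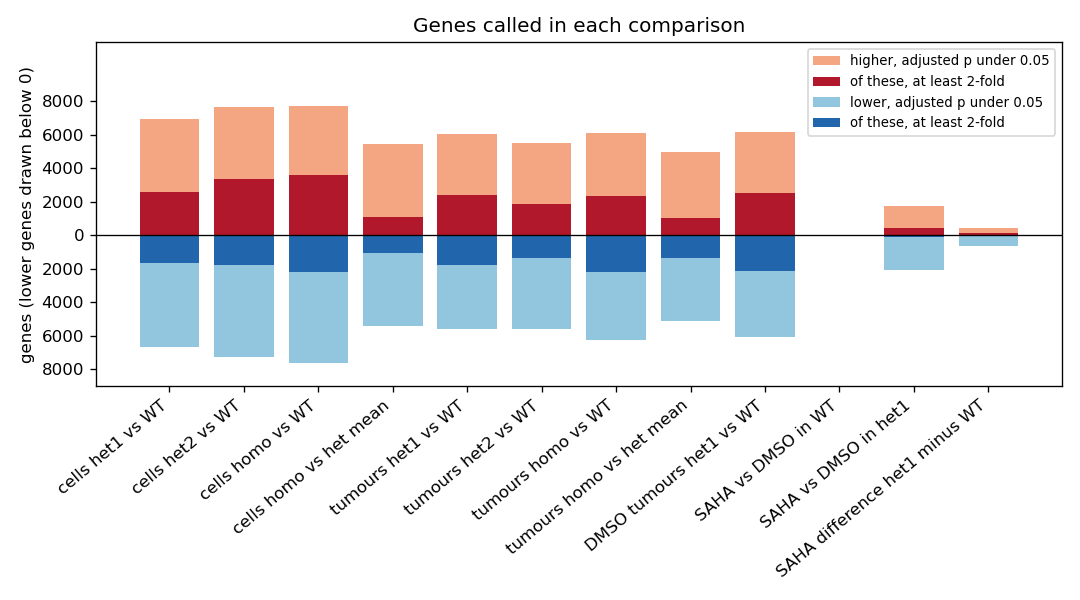
Genes called by edgeR in each of the 12 comparisons (horizontal axis), with the number raised above 0 and lowered below 0 (vertical axis) and the part that changed at least 2-fold in darker colour. Counts run from 0 for SAHA in WT tumours to 7685 raised and 7608 lowered in homo cells.

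Het1 against WT tumours at day 30 asks which differences the first heterozygous line showed when grown as a xenograft (n = 4 per group). The epithelial sodium channel subunit gene SCNN1G rose from 2 counts to 75.1 ± 22.9 CPM, a ratio of 12800 (interval 3550 to 106000), and SCNN1B from 0.499 ± 0.25 to 69.8 ± 11.2 CPM (log2FC 7.13, SE 0.26). DAAM2 rose by a log2FC of 8.31, CT45A1 by 8.03, ELOVL4 by 6.29 and SLC6A15 by 6.1, and CT45A1 belongs to a family of near-identical genes that can share reads. The alcohol dehydrogenase gene ADH1C fell from 29.1 ± 7.23 CPM to 0 counts (at least 2970-fold), and the anion exchanger gene SLC26A3 fell by a log2FC of -11.25. The coactivator gene PPARGC1A fell by -10.36, NTRK3 by -9.43, the tight junction gene CLDN2 from 830 ± 114 to 1.99 ± 0.74 CPM (-8.69) and FOXQ1 by -8.52. EdgeR called 6032 genes raised and 5580 lowered.

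Stem cell associated genes were lower in het1 tumours (1 raised and 10 lowered of 12; median log2FC -1.11; adjusted p = 0.000598, and adjusted p = 0.0294 with an estimated correlation): CD44 fell from 770 ± 43.5 to 253 ± 18.4 CPM, and ALDH3A1, NOTCH3 and NOTCH1 fell. CDH1, which encodes E-cadherin, fell from 385 ± 20.1 to 142 ± 13.1 CPM, and EPCAM, KRT8 and KRT19 fell with it (14 of 18 epithelial genes lowered; adjusted p = 3.84e-06, and adjusted p = 0.22 with an estimated correlation). The keratinocyte markers had 5 of 5 lowered, with KRT6A falling from 56.6 ± 11.2 to 0.636 ± 0.191 CPM (adjusted p = 0.00195, and adjusted p = 0.188 with an estimated correlation). MHC class II genes had 6 raised and 2 lowered of 9, with HLA-DMA rising from 15.3 ± 1.49 to 92.2 ± 7.67 CPM (adjusted p = 0.0149, and adjusted p = 0.393 with an estimated correlation). Fibroblast markers stood at 2.28 to 3.02 log2 CPM in het1 and 1.46 to 1.99 in WT (6 of 11 raised; adjusted p = 0.156), and myeloid markers at -0.67 to -0.16 and 0.16 to 0.37 (1 raised and 3 lowered of 8; adjusted p = 0.364). The granin gene CHGB rose from 126 ± 28.3 to 4550 ± 612 CPM, and DLL3 and SYP rose (5 of 9 neuroendocrine genes raised, 1 lowered; adjusted p of the list = 0.0288, and adjusted p = 0.22 with an estimated correlation). Among 20 hypoxia genes 11 rose, including P4HA1, ERO1A and ANGPTL4, while CA12 fell 3.13-fold (adjusted p = 0.00596, and adjusted p = 0.658 with an estimated correlation).

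Het2 against WT tumours at day 30 (n = 4 per group) put the same question to the second heterozygous line. SCNN1G rose to 15.4 ± 4.34 CPM, a ratio of 2640 (interval 729 to 21800), COL14A1 from 0.458 ± 0.172 to 105 ± 49 CPM (log2FC 7.84), LRP1B by 6.68, SLITRK6 by 6.19, the apolipoprotein gene APOD by 5.69 and SLC16A6 by 5.15. The monoamine oxidase gene MAOB fell by a log2FC of -8.54, SLC26A3 by -7.49 and the water channel gene AQP1 from 97.9 ± 15.4 to 1.53 ± 0.439 CPM (-5.99). PEG10 fell by -5.77 and MUCL3 by -5.57. EdgeR called 5493 genes raised and 5591 lowered, and 6488 in all with the marker covariate. The histone gene HIST2H2BE rose from 13 ± 1.83 to 59 ± 6.69 CPM, and CDKN1A, HIST1H1C and CLU rose, within a list of genes that HDAC inhibitors raise (10 of 12 raised; adjusted p = 7.79e-05, and adjusted p = 0.368 with an estimated correlation). The interferon-stimulated genes IFITM1, IFITM3, IFI6 and USP18 rose (17 of 25 raised, 0 lowered; adjusted p = 0.00116, and adjusted p = 0.716 with an estimated correlation), and IFI6 varied widely at 196 ± 166 CPM. Endothelial markers stood at -0.58 to -0.04 log2 CPM in het2 and -1.4 to -0.97 in WT (5 of 9 raised; adjusted p = 0.0776), and myeloid markers at 0.37 to 0.81 and 0.16 to 0.37 (adjusted p = 0.889). Fibroblast markers stood at 1.75 to 2.67 in het2 and 1.46 to 1.99 in WT (3 raised and 1 lowered of 11; camera adjusted p = 0.516). OCLN, EPCAM, KRT19 and CDH1 fell (12 of 18 epithelial genes lowered; adjusted p = 0.000688, and adjusted p = 0.368 with an estimated correlation). MKI67 fell from 237 ± 26.7 to 99.5 ± 17.9 CPM while MCM2 rose 1.46-fold. The cell cycle call behind them (12 of 28 lowered; adjusted p = 0.0253, and adjusted p = 0.894 with an estimated correlation) was lost without WT replicate 1, WT replicate 4 or het2 replicate 0, with adjusted p up to 0.0822.

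Homo against WT tumours at day 30 asks the same of the line labelled homo (n = 4 per group). SCNN1G rose to 62.8 ± 4.04 CPM, a ratio of 10800 (interval 3000 to 89400), MARCOL by a log2FC of 7.25, SCNN1B by 7.1, ELOVL4 by 6.82, CT45A1 by 6.11 and RIMS4 by 6.1. SLC26A3 fell from 51.6 ± 5.79 CPM to 0 counts (at least 5010-fold), and MSC fell from 11 ± 0.415 CPM to 2 counts, a ratio of 1610 (interval 445 to 13300). The neighbouring receptor genes OR51E1 and OR51E2, which may share reads, fell by log2FC of -11.11 and -11.08. ADH1C fell by -10.61 and FOXQ1 by -10.54. EdgeR called 6098 genes raised and 6250 lowered, and 4684 in all with the marker covariate.

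CDH1, EPCAM and KRT19 fell 3.46-fold, 6.65-fold and 18.6-fold in homo tumours, where 15 of 18 epithelial genes were lowered and 0 raised (adjusted p = 1.16e-05, and adjusted p = 0.255 with an estimated correlation). The carbonic anhydrase gene CA12 fell from 1380 ± 136 to 57.4 ± 10.7 CPM, and PFKFB3, SLC2A1 and PDK1 fell (12 of 20 hypoxia genes lowered, 2 raised; median log2FC -0.6; adjusted p = 0.000685, and adjusted p = 0.542 with an estimated correlation). HLA-DMA rose from 15.3 ± 1.49 to 142 ± 4.81 CPM and HLA-DPA1, HLA-DRB1 and HLA-DMB rose (7 of 9 MHC class II genes raised; adjusted p = 0.00329, and adjusted p = 0.255 with an estimated correlation). The endothelial markers EGFL7, CDH5, KDR and ESAM rose (6 of 9 raised; adjusted p = 0.0295, and adjusted p = 0.212 with an estimated correlation), and EGFL7 was at 65.6 ± 6.48 CPM against at most 1.84 CPM for the other 3. Myeloid markers were not called (5 raised and 1 lowered of 8; adjusted p = 0.435), nor were fibroblast markers (6 raised and 1 lowered of 11; adjusted p = 0.132), which averaged 2.55 to 2.91 log2 CPM in homo and 1.46 to 1.99 in WT. Mitochondrially encoded mRNAs had 13 of 13 raised (median 0.56; adjusted p = 0.000878, and adjusted p = 0.629 with an estimated correlation), with MT-CO2 rising from 1220 ± 113 to 2150 ± 179 CPM.

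Genes shared by the 3 lines in day 30 tumours were counted as in culture. SCNN1G rose in each line, and COL14A1, CT45A1, APOD, LRCH2, ELOVL4, CHRD and DAAM2 rose by log2FC of at least 5.78, 5.73, 5.56, 5.4, 5.29, 5.21 and 5.17. SLC26A3 fell from 51.6 ± 5.79 CPM to at most 0.291 ± 0.0982 CPM. AQP1, the transferrin gene TF, the adhesion gene NRCAM, KRT17, MFAP5 and MUC12 fell by log2FC of -5.99, -4.52, -4.52, -4.36, -4.15 and -3.87 or further, KRT17 from 398 ± 82.9 CPM and MUC12 from 952 ± 115 CPM in WT. EdgeR called 2668 genes raised in all 3 lines and 2579 lowered, where independent lists would share 397.9 and 384 and simulated unchanged lines shared 0. As in culture, the simulated 0 covers only noise in the shared WT libraries. Fewer genes were shared with the marker covariate, as given below with the other processing choices. Pairs of lines correlated across genes with r = 0.63, 0.72 and 0.75, against 0.49, 0.48 and 0.49 in simulation. Covariances were 0.819, 1.23 and 1.03, against 0.0282, 0.0283 and 0.0282 in simulation. With different WT libraries for each line of a pair (6 ways of dividing the 4 WT tumours), r ran from 0.55 to 0.69.

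Homo against the mean of het1 and het2 tumours asks whether homo tumours differed from heterozygous ones. MARCOL rose by a log2FC of 6.21 (SE 0.16), TMTC1 by 4.96, GUCY1A2 by 4.08 and B4GALNT2 by 3.51. OR51E1 fell by -6.24 (SE 0.6), ANKRD30A by -5.54, LNCAROD by -5.43 and the cobalamin carrier gene TCN1 by -4.79. EdgeR called 4976 genes raised and 5104 lowered (49.4% raised), and 3554 in all with the marker covariate (44.4% raised). Hypoxia genes had 20 of 20 lowered (median -1.24; adjusted p = 1.36e-15, and adjusted p = 0.201 with an estimated correlation), with CA12 lower by a log2FC of -3.53, PFKFB3 by -1.91, ERO1A by -0.75 and LDHA by -0.47. Interferon-stimulated genes had 21 of 25 lowered and 0 raised (median -1.49; adjusted p = 8.05e-06, and adjusted p = 0.876 with an estimated correlation), with GBP1, OAS1, IFI44 and MX2 lower by -1.98, -1.05, -3.73 and -4.7. Endothelial markers were higher (7 of 9 raised; adjusted p = 0.0265, and adjusted p = 0.201 with an estimated correlation), at -0.05 to 0.19 log2 CPM in homo, -0.58 to -0.04 in het2 and -1.62 to -1.21 in het1. Myeloid markers, at 0.76 to 1.04, 0.37 to 0.81 and -0.67 to -0.16, were not called (5 of 8 raised; adjusted p = 0.182). Mitochondrially encoded mRNAs had 13 of 13 raised (median 0.82; adjusted p = 3.11e-08, and adjusted p = 0.564 with an estimated correlation). The cholesterol synthesis genes IDI1, LSS and DHCR7 rose by 0.53, 0.43 and 0.41 (12 of 21 raised; adjusted p = 0.00805, and adjusted p = 0.876 with an estimated correlation).

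**Figure D3:**
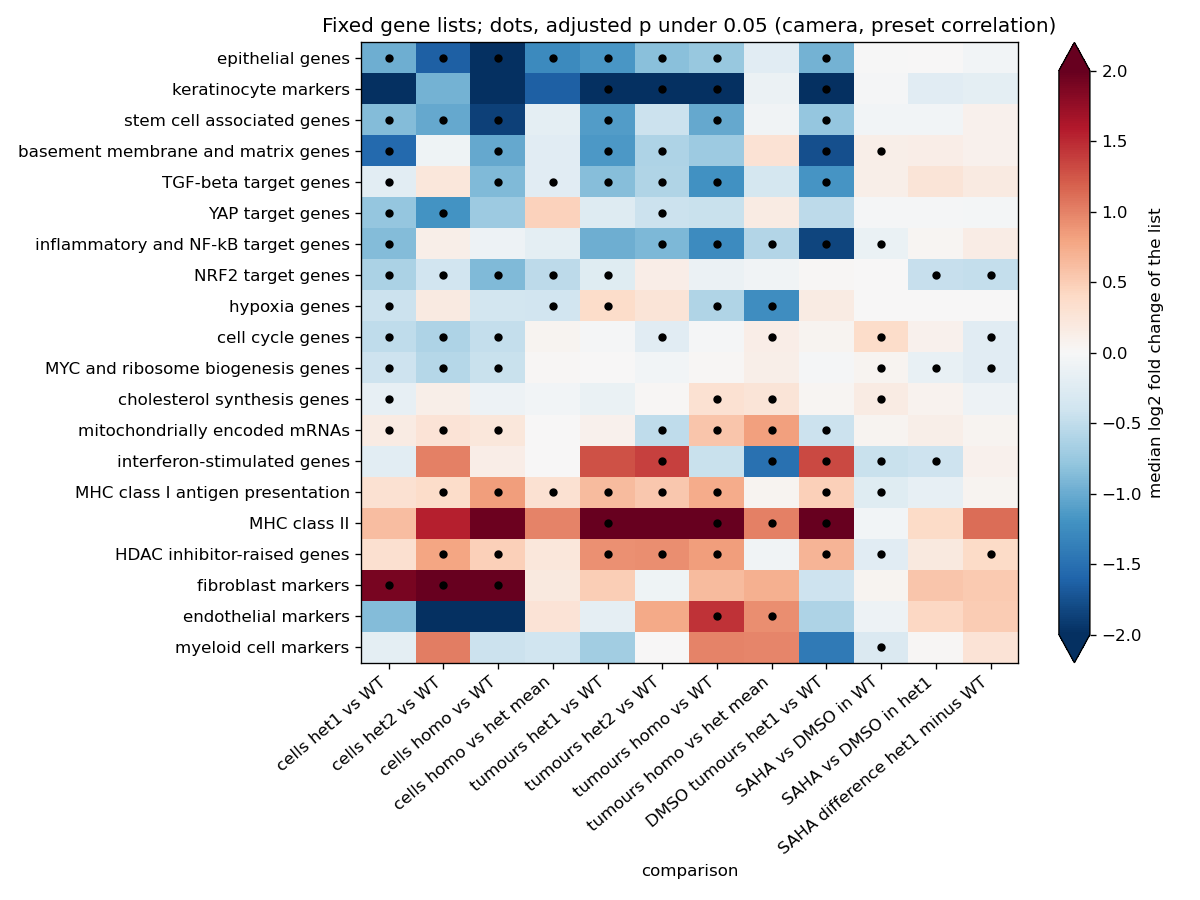
Heat map of the median log2 fold change (colour) of each gene list (vertical axis) in the 12 comparisons (horizontal axis); dots mark lists with a camera adjusted p under 0.05 at the preset correlation. Medians of the epithelial list run from -2.66 in homo cells to 0 for SAHA in het1 tumours.

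Differences in cultured cells were set against those in tumours of the same line, to ask how far culture and xenograft shared them. Among genes tested in both, 52.1% of those raised and 47.5% of those lowered in het1 cells were called the same way in het1 tumours, and 12.4% and 12.2% were called the opposite way. For het2 the same-way shares were 42.5% and 41.3% (opposite 16% and 15.9%), and for homo 46.4% and 44.7% (opposite 17.1% and 16.3%). The 2322 genes raised at least 2-fold in het1 cells had a median log2FC of 1.00 in het1 tumours (camera p = 3.07e-22, and 0.000624 with an estimated correlation), and the 1598 lowered a median of -0.95 (p = 4.95e-29, and 0.000102). The het2 sets of 3011 and 1679 genes had medians of 0.56 (camera p = 7.44e-14, and 0.000907 with an estimated correlation) and -0.55 (camera p = 1.65e-16, and 0.00017). The homo sets of 3193 and 2081 genes had medians of 0.80 (camera p = 1.86e-16, and 0.00117 with an estimated correlation) and -0.80 (camera p = 7.91e-23, and 0.000108). NTRK3, DAAM2 and COL14A1 are examples of genes that changed the same way in both settings. Lists carried over unevenly. Epithelial genes were called lower in all 3 lines in cells (camera adjusted p from 9.99e-05 to 0.0041, and from 0.0327 to 0.0656 with an estimated correlation). They were also called lower in all 3 lines in tumours (camera adjusted p from 3.84e-06 to 0.000688, and from 0.22 to 0.368 with an estimated correlation). NRF2 targets were called in het1 tumours (4 raised, 12 lowered; camera adjusted p = 0.0268, and 0.658 with an estimated correlation), but not in het2 (10 and 5; 0.492) or homo (10 and 9; 0.585). MYC and ribosome biogenesis genes were not called in het1, het2 or homo tumours (0.647, 0.554 and 0.893), nor cell cycle genes in het1 and homo tumours (0.233 and 0.893).

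Het1 against WT tumours under DMSO gave a second set of xenografts of the same lines (n = 4 per group). SCNN1G rose from 0.0159 ± 0.023 to 57.6 ± 3.25 CPM (log2FC 11.55, SE 0.23), DAAM2 by 8.37, SCNN1B by 7.86, CT45A1 by 7.68, the carboxypeptidase gene CPE from 10.7 ± 2.53 to 1350 ± 143 CPM (6.97) and APOD by 6.96. ZBED2 fell from 14.5 ± 5.09 CPM to 1 count, a ratio of 4260 (interval 764 to 168000), PPARGC1A by a log2FC of -11.09, SLC26A3 by -10.8 (SE 1.3), NTRK3 by -10.5, ADH1C by -9.42 and SIRLNT by -9.02. EdgeR called 6158 genes raised and 6047 lowered. Of the genes raised and lowered in het1 tumours at day 30, 78.7% and 75.5% were called the same way here, 0.654% and 0.527% the opposite way, and log2FC correlated with r = 0.9 across genes. As sets, the 2304 raised genes had a median log2FC of 1.73 (camera p = 1.04e-57, and 2.66e-07 with an estimated correlation) and the 1718 lowered a median of -1.75 (p = 4.01e-57, and 9.56e-07).

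CXCL5 fell from 1020 ± 118 to 37.4 ± 6.51 CPM in het1 tumours under DMSO, and CXCL3, CXCL2 and SOD2 fell (13 of 18 inflammatory and NF-kB target genes lowered, 3 raised; adjusted p = 0.000744, and adjusted p = 0.632 with an estimated correlation). The transforming growth factor beta targets TGFBI, ID3 and SMAD7 fell while ID1 rose 1.74-fold (13 of 16 lowered; adjusted p = 0.000497, and adjusted p = 0.494 with an estimated correlation). IFITM3, IFITM1 and OAS2 rose, whereas OAS1 fell 2.69-fold (16 of 25 interferon-stimulated genes raised, 1 lowered; adjusted p = 0.00366, and adjusted p = 0.726 with an estimated correlation). CLDN4, CDH1, KRT7 and EPCAM fell as at day 30 (12 of 16 epithelial genes lowered; adjusted p = 0.000744, and adjusted p = 0.494 with an estimated correlation). Mitochondrially encoded mRNAs had 11 of 13 lowered here (median -0.43; adjusted p = 0.00122, and adjusted p = 0.632 with an estimated correlation). Myeloid markers were not called (1 raised and 6 lowered of 8; adjusted p = 0.0597), and were called without WT DMSO replicate 3 or 7 (adjusted p down to 0.0412).

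SAHA against DMSO in WT tumours asks what the drug changed in tumours of the parental line (n = 4 per group). EdgeR called 0 genes, with 1911 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0792; DESeq2 called 151. FOXM1 was at 37.7 ± 4.7 CPM under DMSO and 49.8 ± 3.34 under SAHA (log2FC 0.40, adjusted p = 0.194), and the replication genes MCM4, MCM5 and MCM3 had log2FC of 0.39, 0.36 and 0.27. Adjusted over the list alone, 28 of 28 cell cycle genes rose and 0 fell (median 0.36; camera adjusted p = 5.91e-37, and adjusted p = 0.121 with an estimated correlation). The interferon-stimulated genes IFIT2, GBP1, OAS2 and IFI6 had log2FC of -0.5, -0.4, -1.05 and -1.02 (median of the list -0.45; adjusted p = 1.62e-07, and adjusted p = 0.609 with an estimated correlation). Myeloid markers were lower beside them (median -0.29; -0.06 to 0.74 log2 CPM under SAHA and 0.62 to 1.03 under DMSO; adjusted p = 0.00962, and adjusted p = 0.434 with an estimated correlation), a call lost without WT SAHA replicate 4 (adjusted p = 0.162). Genes that HDAC inhibitors raise were lower as a list (median -0.23; 4 of 12 fell when adjusted over the list alone; adjusted p = 2.09e-05, and adjusted p = 0.0817 with an estimated correlation), CDKN1C among them at a log2FC of -0.9. Leaving out WT DMSO replicate 3 gave 170 genes, WT SAHA replicate 4 gave 27, and WT DMSO replicate 2 and WT SAHA replicate 6 gave 1 each.

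SAHA against DMSO in het1 tumours asks the same in a truncated line (n = 4 per group). KLHL29 rose from 2.31 ± 0.345 to 8.71 ± 1.08 CPM (log2FC 1.91, SE 0.23), DNM3 by 1.66, C11orf86 by 1.62, NOVA2 by 1.56 and the cytokine gene IL11 by 1.5. PXDN rose by 2.14 (SE 0.65, adjusted p = 0.0396). NEB fell from 66.5 ± 18.4 to 17.7 ± 2.77 CPM (log2FC -1.91, SE 0.33), ADGRG5 by -1.64, the transthyretin gene TTR by -1.57, DCDC1 by -1.44, CYS1 by -1.41 and EDAR by -1.39. The PXDN call was lost in 6 of 8 single omissions (log2FC 1.83 to 2.43), the TTR call in 5 of 8 (-1.71 to -1.48), and the NOVA2 call without DMSO replicate 5 (1.44). With the replicate block the calls of PXDN, NOVA2, IL11, NEB, TTR, DCDC1, CYS1 and FN1 were lost. EdgeR called 1734 genes raised and 2067 lowered, 567 of them at least 2-fold. Of the alternatives, DESeq2 called 4502 genes, the replicate number as a block 812, and the fit without het1 SAHA replicates 2 and 3, added after the data were seen, 1826. The fibronectin gene FN1 fell from 1350 ± 251 to 563 ± 144 CPM.

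NRF2 target genes had 16 of 22 lowered and 0 raised by SAHA in het1 tumours, and 19 lowered when adjusted over the list alone (median log2FC -0.46; adjusted p = 5.83e-16, and adjusted p = 0.438 with an estimated correlation). AKR1C3 fell from 844 ± 101 to 449 ± 50.3 CPM, AKR1C2 from 1460 ± 207 to 746 ± 97.4, GCLM from 127 ± 9.65 to 74.5 ± 8.53 and AKR1C1 from 734 ± 127 to 354 ± 47.7. The ribosome biogenesis genes NCL, RRP12, DKC1 and PES1 fell 1.31-fold, 1.23-fold, 1.24-fold and 1.2-fold (8 of 18 lowered, 3 raised; adjusted p = 0.00865, and adjusted p = 0.931 with an estimated correlation). Interferon-stimulated genes were lower as in WT (median -0.41; 6 of 25 lowered, 0 raised, and 8 lowered when adjusted over the list alone; adjusted p = 0.00158, and adjusted p = 0.931 with an estimated correlation), with IFIT2 falling 1.61-fold. Secreted protease genes were called (2 raised and 1 lowered of 15; adjusted p = 0.0416, and adjusted p = 0.931 with an estimated correlation), but not without DMSO replicate 3, SAHA replicate 1 or SAHA replicate 3 (adjusted p up to 0.0776). With the replicate block the calls of RRP12, DKC1 and PES1 were lost. Genes raised at least 2-fold in het1 tumours at day 30 had a median log2FC of 0.26 under SAHA, with 352 raised and 61 lowered (camera p = 1.91e-09, and 0.00239 with an estimated correlation). The lowered set had a median of -0.02 (157 raised, 210 lowered; camera p = 0.468, and 0.68 with an estimated correlation), but p was 0.000232 for the set of genes lowered at any fold. Fibroblast markers, which het1 cells also expressed in culture (7 of 8 raised against WT), averaged 2.69 to 2.92 log2 CPM under SAHA and 2.16 to 2.48 under DMSO (median log2FC 0.55; 2 raised and 1 lowered of 11; adjusted p = 0.0561, and adjusted p = 0.931 with an estimated correlation), and endothelial markers had a median of 0.42 (adjusted p = 0.352); neither list was called. EdgeR called 2643 genes with the marker covariate.

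The difference between the SAHA effects in het1 and WT tumours asks whether the lines responded differently. TNS4 had a log2FC of 1.79 in het1 and 0.01 in WT (difference 1.78, SE 0.38), but stood at 1.82 CPM in het1 and 206 CPM in WT under DMSO. The kinase gene FYN had 1.12 and -0.44 (difference 1.56, SE 0.2), C11orf86 1.62 and 0.10 (1.52) and DNM3 1.66 and 0.17 (1.48). OR51E1 and OR51E2 differed by -2.75 and -2.49, and the transporter genes SLC17A4 and SLC17A3 had -2.51 and -1.91 in het1 against -0.17 and -0.15 in WT (differences -2.33 and -1.76). The OR51E1 call was lost in 9 of 16 single omissions (difference -3 to -2.44) and the SLC17A4 call in 7 (-2.81 to -2.06). EdgeR called 455 genes with a higher and 611 with a lower SAHA effect in het1, and DESeq2 called 1803. With the replicate number as a block 19 genes were called, 68.4% of them higher against 42.7% without it, and the calls of all genes named here and in the next paragraph were lost. The edgeR count ran from 542 without het1 SAHA replicate 1 to 1677 without WT SAHA replicate 6.

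AKR1C3, GCLM, SLC7A11 and AKR1C2 had a lower SAHA effect in het1 by log2FC of -0.86, -0.82, -0.72 and -0.88 (12 of 22 NRF2 targets lower, 15 when adjusted over the list alone; adjusted p = 4.89e-15, and adjusted p = 0.257 with an estimated correlation). Genes that HDAC inhibitors raise had a higher effect in het1 (median 0.39; 3 of 12 called; adjusted p = 3.87e-05, and adjusted p = 0.0855 with an estimated correlation): the linker histone gene H1F0 differed by 0.57 (0.51 in het1, -0.06 in WT), HIST2H2BE by 0.48 and CDKN1C by 1.38 (0.48 and -0.90). For SAHA in het1 itself this list was not called (median 0.19; 2 raised and 0 lowered of 12; camera adjusted p = 0.0984). Its median in WT was -0.23, so much of the difference came from a fall in WT. The MYC and ribosome biogenesis genes NCL, DKC1, RRP12 and PES1 differed by -0.5, -0.43, -0.33 and -0.28 (5 of 18 lower; adjusted p = 4.94e-06, and adjusted p = 0.434 with an estimated correlation), and the PES1 call was lost without het1 DMSO replicate 3, het1 SAHA replicate 1 or het1 SAHA replicate 3. Cell cycle genes had 2 of 28 lower (adjusted p = 2.94e-07, and adjusted p = 0.732 with an estimated correlation), RRM2 by -0.69 and MCM3 by -0.33; the MCM3 call was lost in 11 of 16 single omissions (-0.38 to -0.28). TIMP2, which inhibits metalloproteases, was the 1 of 15 secreted protease genes with a called difference, 0.42 (adjusted p of the list = 0.0165, and adjusted p = 0.568 with an estimated correlation).

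**Figure D4:**
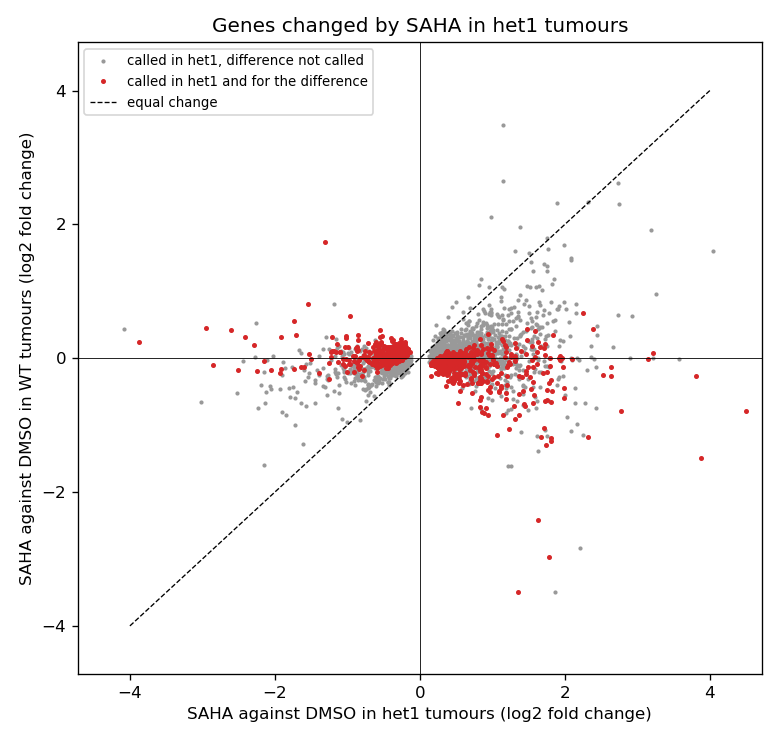
SAHA log2 fold change in WT tumours against that in het1 tumours, with a point for each of the 3801 genes called in het1; red points also had a called difference between the lines. Over these genes the median size was 0.36 in het1, and the median change in WT in the het1 direction was 0.02.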

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

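The tests in this part, including the divisions of the libraries into other groups and the fit without het1 SAHA replicates 2 and 3, were chosen only after the results they examine were seen; the interaction, the comparison of homo with the het lines, the gene lists and the replicate block were planned.

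Of 134 groups of 4 libraries examined for a library that stood apart from the other 3, 12 had one, and chance marks about 1 in 20 such groups (6.7 here). EP300 stood at 136 CPM in het1 SAHA replicate 3 (117 to 119 in the others) and at 82.9 in WT tumour replicate 4 (90.2 to 91.4). CREBBP stood at 98 CPM in WT DMSO replicate 7 (109 to 110) and at 109 in homo tumour replicate 1 (95.4 to 96.7). CPE was at 14.5 CPM in WT DMSO replicate 3 (9.02 to 9.75), CT45A1 at 50.5 in het1 tumour replicate 2 (39.9 to 40.9), DAAM2 at 15.9 in het1 tumour replicate 3 (18.7 to 18.8) and at 3.15 in homo tumour replicate 4 (2.04 to 2.14). MSC was at 10.4 CPM in WT tumour replicate 2 (11.2 in the others), MUC12 at 43.8 in het1 tumour replicate 3 (20.1 to 22.6), NRCAM at 64.8 in WT tumour replicate 2 (79.5 to 81) and TF at 58.4 in WT tumour replicate 0 (21.2 to 26.7).

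Tested differences between lines were found for 10826 genes between homo and the het mean in cells, 10080 in day 30 tumours and 1066 for the SAHA effect. By name, the SAHA effect differed between het1 and WT for TNS4 (1.78), FYN (1.56), C11orf86 (1.52), DNM3 (1.48), OR51E1 (-2.75), OR51E2 (-2.49), SLC17A4 (-2.33) and SLC17A3 (-1.76). With the replicate block 19 genes were called for the SAHA effect, and the calls of these named genes were lost. As lists it differed for NRF2 targets (adjusted p = 4.89e-15, and adjusted p = 0.257 with an estimated correlation), cell cycle genes (2.94e-07, and 0.732), MYC and ribosome biogenesis genes (4.94e-06, and 0.434), secreted protease genes (0.0165, and 0.568) and genes that HDAC inhibitors raise (3.87e-05, and 0.0855). No list kept its call for the SAHA difference with an estimated correlation.

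Other divisions of the same libraries showed where a chance assignment of these libraries to groups can be excluded, and chance means only this here. Libraries of a group may not be separate cultures or animals. The divisions also cannot exclude chance differences between single lines. The smallest share that 35 divisions can give is 1 of 35. For het1, het2 and homo cells the 10 splits are too few, with 13640, 14858 and 15293 genes in the real split (1 of 10 as large) and 0 as the highest other. Chance was excluded for genes shared by the 3 lines in cells (9124, highest other 202, 1 of 100) and in tumours (5247, highest other 0, 1 of 100), for het1 tumours (11612, highest other 0), het2 tumours (11084, highest other 1), homo tumours (12348, highest other 0) and het1 under DMSO (12205, highest other 0), each 1 of 35. It was excluded for homo against the het tumours (10080, highest other 3328, 1 of 100) and for SAHA in het1 (3801, highest other 1, 1 of 35). The divisions for homo tumours were a draw of 100, and the highest other mixed the lines. They do not show whether a het line in the place of homo would give as many genes. For homo against the het cells 3 of 84 splits gave as many as the real 10826, so chance was excluded; the highest other, 11990, set a het line in the place of homo, so that count is not special to homo. For SAHA in WT 35 of 35 splits gave at least the real 0 genes, with 9 as the highest other; edgeR left 1911 genes at an unadjusted p under 0.05 and DESeq2 called 151. For the SAHA difference 5 of 100 splits gave at least 1066 genes, with 1945 as the highest other. The other 4 kept the het1 treatment groups unmixed and regrouped WT tumours, so they held the het1 change itself, and the highest with mixed het1 groups was 0. These splits therefore do not decide whether chance can be excluded for the difference.

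SAHA changed 3801 genes in het1 tumours and 0 in WT tumours by edgeR (1911 at an unadjusted p under 0.05, and 151 by DESeq2), and the het1 count was 812 with the replicate block and 1826 without het1 SAHA replicates 2 and 3. Single WT libraries that hide a change were argued against as the whole cause, since the highest count without a library was 170 (without WT DMSO replicate 3). The same change hidden by a larger spread was argued against. The median WT change in the het1 direction was 5 percent of the het1 size (-0.0471 to 10.1 percent without single libraries). The median SE was 0.135 in het1 and 0.136 in WT, but the fit shared its estimate of spread between all groups. These SEs therefore cannot compare the spread of the lines. With only the groups compared in the fit, edgeR called 5178 genes in het1 and 0 in WT. With the marker covariate 2643 genes were called, so the marker mean did not account for most calls. That covariate is partly tumour cell RNA, as set out below for interferon-stimulated genes. It therefore cannot decide whether the share of host cells changed. A different response of the lines may underlie the pattern; the interaction that tests it called 1066 genes, but 19 with the replicate block. A different drug exposure of the tumours of each line was not tested.

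Hypoxia genes were lower in homo than in het tumours (median log2FC -1.24, quartiles -1.63 to -0.8; 20 of 20). With the marker covariate the median was -1.06 (16 of 20 called), so the marker mean did not account for the pattern. The covariate is partly tumour cell RNA, so a different share of host cells stays open. In cells the list was lower too (median -0.39; 4 raised and 14 lowered of 20; camera adjusted p = 0.00228, and adjusted p = 0.207 with an estimated correlation). Part of the pattern was thus present in culture, where LDHA was lower by more (-0.66) than in tumours. The smaller median in cells argued against a property of the cultured lines as the whole cause. Tumour size, necrosis and time from collection to lysis were not examined and stay open, as does a difference between the lines in how they grow; the list was not called with an estimated correlation (adjusted p = 0.201).

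Interferon-stimulated genes were lower in homo than in het tumours (median log2FC -1.49, quartiles -1.78 to -0.8, median SE 0.35; 21 of 25). With the marker covariate the median was 0.08 (quartiles -0.5 to 0.39, median SE 0.3), so the folds moved and the errors did not grow. No list test was run with the covariate. In covariate fits without single libraries, 2 to 6 of 25 members were still called lowered and 0 or 1 raised. Without het2 tumour replicate 4 the median was -0.35. Because the marker mean largely followed the groups, the covariate cannot decide whether a different share of host cells accounts for the pattern. Marker means of single tumours were 0.38 to 0.69 log2 CPM in het1, 0.69 to 1.21 in het2 and 1.2 to 1.49 in homo. Marker and interferon means did not follow one another across groups. In WT, het1, het2 and homo tumours, markers averaged 0.33, 0.54, 1.03 and 1.34 log2 CPM and interferon genes 2.09, 3.18, 3.69 and 1.96. Homo tumours thus had the highest marker mean and the lowest interferon mean. A property already present in culture was argued against as the whole cause, since the median in cells was 0.01. Members went both ways there (quartiles -0.94 to 0.3; 5 raised and 9 lowered of 21), and OAS1 was lower (-1.52). In at least 1 group of cultured cells 6 of 12 fibroblast, 2 of 12 endothelial and 2 of 16 myeloid markers were at 1 CPM or more, and fibroblast markers averaged 0.57 to 1.96 log2 CPM in het and homo cells, so the covariate is partly tumour cell RNA.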

How the results depend on the processing

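The tests without WT SAHA replicates 4 and 6, without het1 SAHA replicates 2 and 3, and of the het1 tumour sets in WT tumours were chosen only after the data were seen; the others were planned. With a log2FC of at least 1, counts were 4253, 5137 and 5775 in het1, het2 and homo cells and 2167 for homo against het cells. They were 4169, 3169, 4511 and 2364 for the same comparisons in tumours, 4619 under DMSO, 567 for SAHA in het1, 216 for the SAHA difference, 2676 for genes changed the same way in all 3 lines in cells, and 1708 for genes changed the same way in all 3 lines in tumours at day 30. With the marker covariate het2 tumours had 6488 genes, homo tumours 4684, homo against het tumours 3554, the genes changed the same way in tumours 2840 and SAHA in WT 62. SAHA in WT gave 36 genes with no filter, 151 by DESeq2, 2 without WT SAHA replicates 4 and 6, and 0 to 170 without single libraries; edgeR called 0, with 1911 at an unadjusted p under 0.05. SAHA in het1 gave 812 genes with the replicate block and 1826 without het1 SAHA replicates 2 and 3. The SAHA difference gave 1803 genes by DESeq2, 19 with the replicate block, 407 without het1 SAHA replicates 2 and 3, and 542 to 1677 without single libraries. The set of genes lowered in het1 tumours had camera p, at the preset correlation, of 0.937 with the block and 0.000232 over all genes under SAHA in het1, and 0.4 and 0.902 in WT, where single omissions gave 0.0295 to 0.718; the raised set in WT gave 0.137 to 0.964. List calls numbered 14 with an estimated correlation, 210 by fry and 116 to 126 without single libraries. Inflammatory genes under SAHA in WT reversed direction without WT SAHA replicate 4 (adjusted p = 0.326, range 8.33e-08 to 0.429). RLE left all 27 counts and set tests the same; RLE left 787 results on genes the same, and DESeq2 gave 775 the same and 11 stronger; the replicate block gave 740 the same, 44 weaker, 1 stronger and 2 moved, and single omissions 6109 the same, 92 weaker, 13 stronger and 14 moved. The block adds terms for the replicate numbers, and 13 of the 16 treated libraries share their number with another library. The rest are fitted by a term of their own, so less is left to measure the spread. Whether the block's effect goes beyond this loss was not tested.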

Other observations

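The tests here were planned; the remarks on single genes were chosen by the naming rule except the skeletal muscle markers, which were looked at after the data were seen. FOXA2, a lung and gut lineage transcription factor gene, fell in cultured het1, het2 and homo cells by log2FC of -2.92, -4.18 and -8.55, and the mucin gene MUC5B by -4.9, -7.42 and -11.32. The lung lineage list had 5 raised and 6 lowered of 11 in het1 and homo and 4 and 7 in het2 (adjusted p = 0.134, 0.505 and 0.0328, and adjusted p = 0.231 with an estimated correlation in het2). In tumours FOXA1 rose by 1.45, 1.12 and 1.66 in the 3 lines and by 1.69 in het1 under DMSO, while FOXA2 fell. EGR1, an immediate early gene, rose in cells by 4.86, 4.45 and 5.37, within a list that was not called (adjusted p = 0.503, 0.611 and 0.81). The receptor gene NRP2 fell by -5.4, -2.95 and -7.72 and the growth factor gene VEGFC rose by 2.47, 1.59 and 2.35, in an angiogenesis list called in het1 alone (adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation). In homo cells its adjusted p was 0.0626, and it was called without WT replicate 2, WT replicate 3 or homo replicate 1 (down to 0.0421).

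Acetyltransferase, deacetylase and coactivator genes had 14, 14 and 13 of 24 raised in het1, het2 and homo cells (adjusted p = 0.111, 0.246 and 0.0721), EP300 among them. Mitochondrially encoded mRNAs had 8, 12 and 10 of 13 raised in cells (adjusted p = 0.0102, 0.000744 and 0.00311, and adjusted p = 0.54, 0.463 and 0.539 with an estimated correlation), whereas in tumours 11 of 13 fell in het2 (adjusted p = 0.00652, and adjusted p = 0.716 with an estimated correlation) and 13 of 13 rose in homo (adjusted p = 0.000878, and adjusted p = 0.629 with an estimated correlation). Skeletal muscle markers varied within groups, from a mean log2 CPM of -3.6 to 1.71 in WT tumours, from -3.57 to 1.84 in homo tumours and from -3.36 to 3.62 in WT tumours under DMSO.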
